A study of Gasterosteus aculeatus with 29 samples.

How the data were processed

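Whole-brain RNA of three-spined stickleback (Gasterosteus aculeatus) was profiled by poly-A-enriched, single-end RNA sequencing, per the labels' protocols. The 29 libraries came from individual fish of 10 fathers. The labels give each fish's father, the father's exposure to predation risk while he cared for his brood, the fish's own exposure as a juvenile, and its sex. Libraries were grouped by these labels into neither exposure (n = 5), paternal exposure only (n = 8), personal exposure only (n = 9) and both exposures (n = 7), and numbered within a group in deposition order. The labels' protocols state 9 fish for paternal exposure only. One of them was not analysed here. The sequencing lane was read from the library titles, which name 5 lanes.

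The authors worked with CASAVA 1.8.2, TopHat2 2.0.8, HTSeq 0.6.1 and edgeR, whose version is not given, per the submitters' processing notes. The build those notes name is NCBIM37, a mouse assembly name that does not go with the stickleback gene identifiers of the table. The genome build and annotation release behind the values are therefore not given in the sources used here, and no coordinates are reported. The authors deposited a single table of log2 CPM values (log2 of reads divided by a scaled library size, with a small prior) for 17730 genes. Whether counting used strand is not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical paralogs, cannot be assigned with certainty.

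The lowest deposited log2 value was -6.77 in every library. This floor equals 0 reads plus a prior of 0.25 reads at the mean library size. Above the floor, values on the linear scale rose in whole steps within each library. Dividing by the step gave whole reads for 100% of values within a tolerance of 0.01 reads, the largest distance being 1.26e-08 reads. The recovered reads gave each library's depth in the table, from 2244609 to 55155451 reads (median 8121703). PCR copies were not told apart by molecular identifiers, so read counts describe counting error only. Fold changes on the log2 scale with its prior understate the change of genes with few reads.

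Genes with log2 CPM above 0 in at least 5 libraries were tested, which left 16660 genes. The main test was limma-trend (limma 3.58.1, statmod 1.5.0, R 4.3.3) on the deposited log2 values, with the 4 group means and sex in a single fit over all libraries. Father entered as a random block, with a consensus sibling correlation of 0.111 over genes. Fathers are nested in paternal exposure, so a fixed block for father cannot be fitted to paternal comparisons. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. Differences between the sexes in the exposure effects came from a fit of group-by-sex means. In pairs of libraries, deviations from the group and sex means correlated with a mean r of 0.0633 over 30 pairs with the same father and -0.0399 over 376 pairs with different fathers. The mean r was -0.0326 within lanes and -0.0322 between lanes.

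Pairs of libraries were checked for reads deposited under more than 1 name. The closest pair, neither replicate 5 and personal only replicate 5, differed by 1.86 times the variance of read sampling, and both were kept as separate libraries.

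No source used here pairs the gene identifiers with symbols. The reference table, of assembly fGasAcu3.hap1.1, matched 0 of them, so the gene lists fixed beforehand were not tested. For that case the rule for named genes, set before the data were examined, allows at most 2 identifiers higher and 2 lower per comparison. These were the largest changes among genes past the threshold with a mean log2 CPM of at least 1, or the smallest p-values where none passed. A few genes outside this rule are marked as chosen after their values were seen.

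The comparisons, the test, the gene filter and most alternatives were fixed before the data were examined. Alternatives covered the father block, sex and lane terms, gene filters, normalization, the prior variance, library weights, the threshold, the groups in the fit, and leaving out each neither library or each father. Alternatives added after seeing the data left out libraries that stood apart or ran limma-voom on the recovered reads. Correlations between comparisons that share the neither libraries were set beside 100 simulated sets without effects, made by random signs on each library's residuals. The signs do not keep the resemblance of siblings, and the simulated sets were fitted without the father block that the real values have. Correlations were also computed with the 5 neither libraries divided between the comparisons, by least squares with sex and no father block.

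The main test was tested on simulated data for the 16660 genes. In each run 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. Beyond read sampling, a gene's noise was equally wide in every library and independent of other genes. No simulated library therefore stood apart from the rest, so the shares may not hold for the real libraries. The runs also gave 6 to 9 false calls each. For paternal only versus neither the main test recovered 37.3% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 80.3% of those changed 4-fold. For personal only versus neither the shares were 61.2%, 77.6% and 92.4%. For both versus neither they were 29.9%, 79.1% and 80.3%, for the interaction 20.9%, 52.2% and 83.3%, and for female versus male 71.6%, 86.6% and 97.0%.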

Results

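Gene expression was measured in whole brains of three-spined stickleback in a factorial design that crossed the father's experience of predation risk with the offspring's own. Fathers were exposed (5 fathers) or not exposed (5 fathers) to predation risk while they tended their young. Offspring then were or were not exposed themselves. The libraries of fathers M9, M31 and M41 came from 1 personal condition each, and those of the other fathers from both. Libraries were available from 5 fish with neither exposure (3 fathers), 8 with paternal exposure only (5 fathers), 9 with personal exposure only (5 fathers) and 7 with both (4 fathers). The labels name 16 fish as female and 13 as male. Values are log2 CPM as deposited, and differences are given with the standard error of the limma fit.

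The gene table held 3313717 to 20965092 reads per library in neither, 4316374 to 26896865 in paternal only, 2844706 to 47411814 in personal only and 2244609 to 55155451 in both. Library neither replicate 3 (father M8, male, lane 4, 4422208 reads) stood apart from the rest. Its relative log spread, the interquartile range over genes of its difference from the median library, was 1.52 log2 units, against 0.249 to 0.481 in the other libraries. Summed over genes, its values came to 61.2% of the scaled library size, whereas the median of the other libraries was 45.8%.

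**Figure D1:**
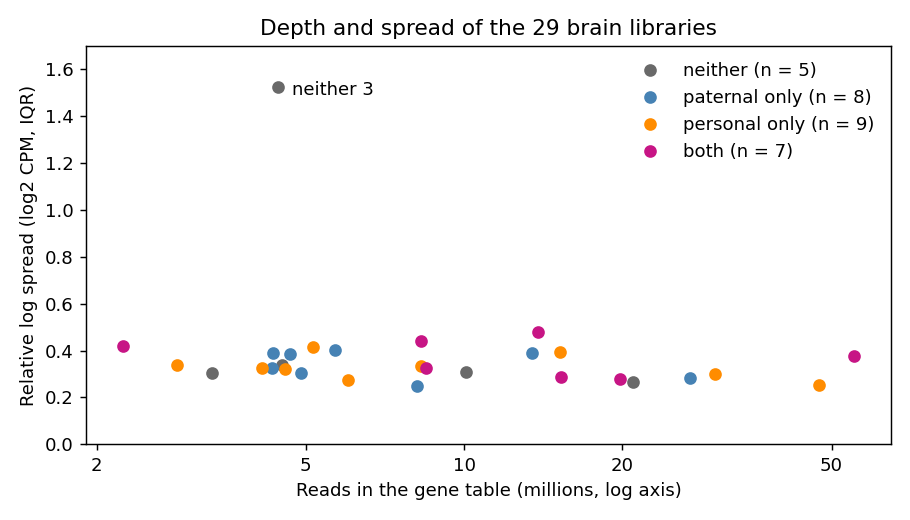
Reads in the gene table per library (x axis, log axis) against the relative log spread (y axis, interquartile range in log2 CPM), 1 point per library, coloured by group. Neither replicate 3 lies at 1.52, and no other library exceeds 0.481.

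Paternal exposure alone was compared with neither exposure to ask what the father's experience changes in offspring that met no predation risk themselves. No gene passed the adjusted threshold in limma. The smallest p-value belonged to ENSGACG00000013161, with 3.63 ± 0.31 log2 CPM (SD, n = 8) in paternal only and 2.59 ± 0.52 (SD, n = 5) in neither, a difference of 0.98 ± 0.18 (SE) at an adjusted p of 0.126. For this gene neither replicate 3 had 1.68 log2 CPM and the other neither libraries 2.72 to 2.92. ENSGACG00000020611 had 2.28 ± 0.41 against 1.12 ± 0.57, a difference of 1.13 ± 0.22 (adjusted p = 0.129). With lower values in paternal only, ENSGACG00000013097 differed by -0.43 ± 0.092 and ENSGACG00000011581 by -0.74 ± 0.16 (adjusted p = 0.178 for each). At an unadjusted p under 0.05 there were 3511 genes, where a share of 0.05 of the genes tested is 833. Genes are correlated, so counts without any effect can lie far from 833, and their range was not computed. Limma-voom on the recovered reads also called 0 genes. Without neither replicate 3 the number at an unadjusted p under 0.05 was 1261. Leaving out neither replicate 5 gave 3 called genes, and leaving out father M11 gave 2.

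Personal exposure alone was compared with neither exposure among offspring of unexposed fathers. Again limma called 0 genes, as did limma-voom. ENSGACG00000020611 had 2.07 ± 0.28 log2 CPM (SD, n = 9) in personal only, a difference from neither of 0.94 ± 0.20 (adjusted p = 0.213). ENSGACG00000016862 had 3.13 ± 0.26 (SD, n = 9) against 2.22 ± 0.60 (SD, n = 5), a difference of 0.86 ± 0.19 (adjusted p = 0.213). Lower values in personal only were seen for ENSGACG00000007219, with -0.49 ± 0.12, and ENSGACG00000004905, with -0.44 ± 0.11 (adjusted p = 0.213 for each). The number of genes at an unadjusted p under 0.05 was 3410 with all libraries and 647 without neither replicate 3. The latter lay below 833, a share of 0.05 of the genes tested. Leaving out neither replicate 2, the other male of father M8 in the group, gave 975 called genes, 652 of them higher, and 5529 at an unadjusted p under 0.05. That fit kept neither replicate 3. Leaving out all libraries of father M8, neither replicates 2 and 3 among them, gave 0 called genes.

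Fish with both exposures differed from fish with neither in 2 genes, both higher. ENSGACG00000020611 had 2.41 ± 0.40 log2 CPM (SD, n = 7) in both and 1.12 ± 0.57 (SD, n = 5) in neither, a rise of 1.28 ± 0.22, or 2.43-fold (adjusted p = 0.0356). ENSGACG00000005494 had 2.63 ± 0.40 against 1.36 ± 0.49, a rise of 1.22 ± 0.22, or 2.32-fold (adjusted p = 0.0356). Each gene had few reads, from 8 to 820 per library for ENSGACG00000020611 and from 12 to 653 for ENSGACG00000005494. No gene was called lower. The smallest p-values on that side belonged to ENSGACG00000004711, with -0.61 ± 0.13, and ENSGACG00000010285, with -0.76 ± 0.16 (adjusted p = 0.161 for each). For ENSGACG00000010285 neither replicate 3 had 5.53 log2 CPM and the other neither libraries 4.44 to 4.72. At an unadjusted p under 0.05 there were 3298 genes with all libraries and 1434 without neither replicate 3. Both calls were lost with 1 value per father and personal condition (adjusted p = 0.171 and 0.189), on leaving out any father but M11 and M33, without neither replicate 3, without neither replicate 1, with lane as a term and in limma-voom, where 0 genes were called. Over the alternatives the rises stayed at 0.97 to 1.46 and 0.87 to 1.35, with adjusted p from 0.00631 to 0.505 and from 0.0247 to 0.505, and 1 gene was called without neither replicate 4 or without neither replicate 5. ENSGACG00000005494 was also lost without father M11 (adjusted p = 0.0564) and under library weights (adjusted p = 0.0854). In alternatives chosen after seeing the data, ENSGACG00000020611 passed without neither replicate 3 and both replicate 7 (adjusted p = 0.0303), and both genes passed without these and personal only replicate 5 (adjusted p = 0.0374 for each).

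**Figure D2:**
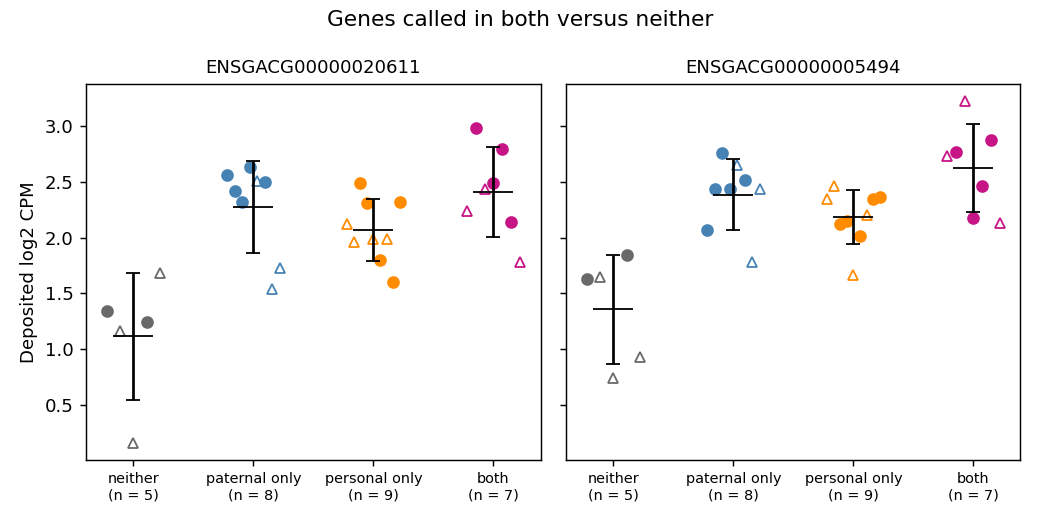
Deposited log2 CPM (y axis) of ENSGACG00000020611 and ENSGACG00000005494 by group (x axis), 1 point per library (filled circles for fish labelled female, open triangles for male), with the group mean and SD in black. Group means in neither were 1.12 and 1.36, and those of the other groups lay between 2.07 and 2.63.

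The interaction of paternal and personal exposure tests whether the effects of the cues add on the log2 scale. Limma called 0 genes. ENSGACG00000015268 came closest on the negative side, with -0.08 ± 0.82 log2 CPM in neither (SD, n = 5), 1.28 ± 0.69 in paternal only (n = 8), 1.28 ± 0.93 in personal only (n = 9) and 0.32 ± 0.54 in both (n = 7), an interaction of -2.04 ± 0.48 (adjusted p = 0.459). Limma-voom called this gene, at -2.68 ± 0.45 (adjusted p = 0.029), and no other. ENSGACG00000016862 had an interaction of -0.96 ± 0.26. Positive estimates led with ENSGACG00000013097, at 0.48 ± 0.11, and ENSGACG00000016177, at 1.03 ± 0.25 (adjusted p = 0.459 for each of these genes). The count at an unadjusted p under 0.05 was 1797 genes with all libraries, 706 without neither replicate 3 and 3860 without neither replicate 2. Because no gene was called in either single-exposure comparison, additivity among called genes has no value.

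Among offspring of exposed fathers, personal exposure (both versus paternal only) gave 0 called genes in limma and in limma-voom, with 321 genes at an unadjusted p under 0.05 and 595 without neither replicate 3. ENSGACG00000016981 had 3.68 ± 0.33 log2 CPM (SD, n = 7) in both and 3.07 ± 0.28 (SD, n = 8) in paternal only, and ENSGACG00000004711 had 4.34 ± 0.16 against 4.81 ± 0.22 (adjusted p = 1 for each). Among personally exposed fish, paternal exposure (both versus personal only) likewise gave 0 called genes in limma, with 732 genes at an unadjusted p under 0.05. At an unadjusted p under 0.01 in limma there were 136 genes with all libraries and 207 without neither replicate 3. ENSGACG00000009971 had 2.75 ± 0.27 log2 CPM (SD, n = 7) in both and 1.96 ± 0.27 (SD, n = 9) in personal only, a difference of 0.78 ± 0.14 (adjusted p = 0.111). This gene passed at 0.77 ± 0.13 without neither replicate 3 (adjusted p = 0.0215). Limma-voom called 2 genes, ENSGACG00000009971 at 0.69 ± 0.12 and ENSGACG00000006113 at 1.78 ± 0.32 (adjusted p = 0.0474 for each), the latter named after its values were seen. With 1 value per father and personal condition, limma called 0 genes here (smallest adjusted p = 0.71). With lane as a term it also called 0 (smallest adjusted p = 0.524), so these calls do not hold at the level of fathers. The direct comparison of paternal only with personal only gave 0 called genes in limma and in limma-voom and 374 at an unadjusted p under 0.05 (583 without neither replicate 3). Its leading genes were ENSGACG00000013087, with a difference of 0.37 ± 0.080, and ENSGACG00000018306, with -0.85 ± 0.22 (adjusted p = 1 for each). The counts of 321, 732 and 374 lay below 833, a share of 0.05 of the genes tested. All groups share an estimate of the spread per gene in the fit, so neither replicate 3 can bear on these comparisons too. The 0 calls in limma carry this limit.

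Averaged over personal exposure, paternal exposure gave 0 called genes in limma and in limma-voom, with 2182 genes at an unadjusted p under 0.05. ENSGACG00000020611 had an average difference of 0.74 ± 0.15, and ENSGACG00000010285 one of -0.49 ± 0.11 (adjusted p = 0.289 for each). The latter gene had 5.53 log2 CPM in neither replicate 3 and 4.44 to 4.72 in the other neither libraries. Without neither replicate 3 a single gene was called, ENSGACG00000006877, at 0.25 ± 0.039 (adjusted p = 0.0153), named after its values were seen. With all libraries and 1 value per father and personal condition, limma called 0 genes (smallest adjusted p = 0.448). Averaged over paternal exposure, personal exposure gave 0 called genes in limma and in limma-voom, with 1247 at an unadjusted p under 0.05, 506 without neither replicate 3, 1951 without neither replicate 1 and 3008 without neither replicate 2. ENSGACG00000000289 had an average difference of 0.58 ± 0.14, and ENSGACG00000014113 one of -0.51 ± 0.13 (adjusted p = 0.586 for each).

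**Figure D3:**
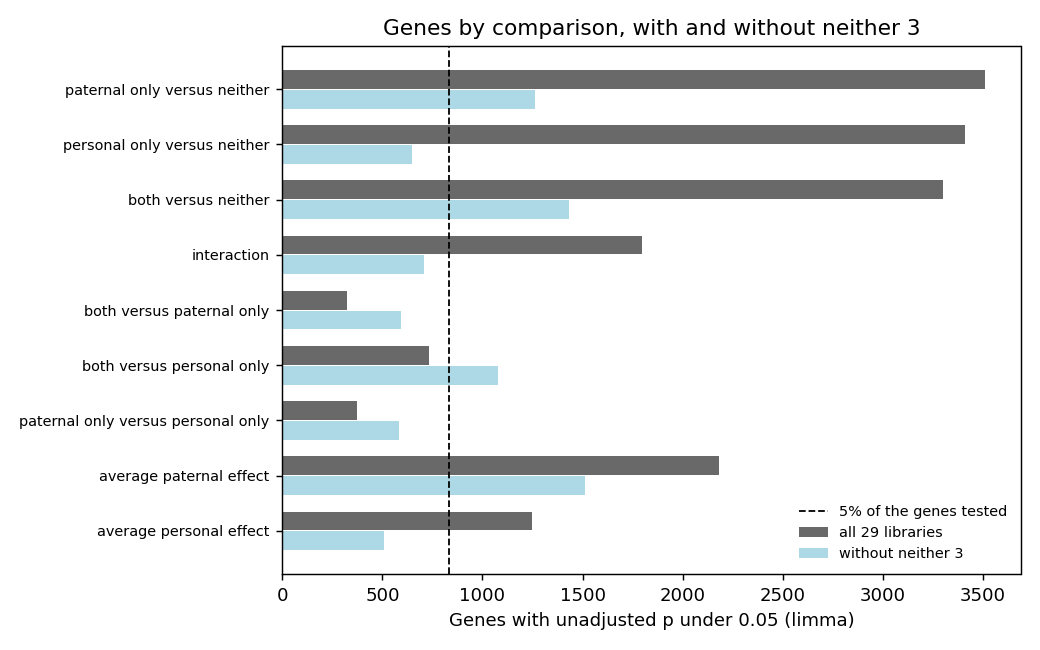
Genes with an unadjusted p under 0.05 in limma (x axis) for each comparison of exposures (y axis). Dark bars are for all 29 libraries and light bars leave out neither replicate 3. The dashed line marks 833 genes, a share of 0.05 of the genes tested. Bars for the comparisons with neither fall from 3511, 3410 and 3298 genes to 1261, 647 and 1434.

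Fold changes of the comparisons with neither were correlated across genes, which are not independent replicates. Pearson's r was 0.771 between paternal only and personal only, 0.77 between paternal only and both, and 0.73 between personal only and both. These comparisons share the neither libraries, and simulated sets without effects gave mean r values of 0.633, 0.627 and 0.629. Of the 100 simulated sets, 29, 27 and 41 gave an r at least as high. The covariances were 0.113, 0.138 and 0.109, against simulated means of 0.0843, 0.0859 and 0.085, with 24, 10 and 30 simulated sets as high. Without neither replicate 3 they were 0.0559, 0.0846 and 0.062, with 70, 43 and 69 simulated sets as high. With the neither libraries divided between the comparisons, the median r over 20 divisions was 0.148, 0.228 and 0.119. No call was shared at the adjusted threshold. At an unadjusted p under 0.01, paternal only and personal only shared 250 higher and 117 lower genes, where independent lists would share 14.7 and 6.59 and simulated sets without effects shared 324 on average in both directions together. Paternal only and both shared 286 higher and 173 lower genes (independent lists 17.0 and 9.53, simulated 297 together). Personal only and both shared 197 higher and 91 lower genes (independent lists 17.0 and 5.69, simulated 307 together). None went in opposite directions in any of these pairs. The shared neither libraries make equal directions likely, so this says nothing about shared effects of exposure. Without neither replicate 3 the shared genes in both directions together fell to 48, 102 and 27, against simulated means of 29, 26.2 and 27.6. The 102, of paternal only and both, lay above the third highest simulated value of 79, and the others below theirs of 108 and 119.

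Sex, which the design does not compare, served to check the labels, and with all libraries more genes were called by sex than in any exposure comparison. Limma called 525 genes, 457 higher in females and 68 lower. ENSGACG00000014118 was higher in females by 1.89 ± 0.21 (adjusted p = 1.11e-07), and ENSGACG00000010422 by 1.76 ± 0.22 (adjusted p = 1.09e-06). ENSGACG00000013963 had 0.93 ± 1.25 log2 CPM (SD, n = 16) in females and 4.20 ± 1.38 (SD, n = 13) in males, a difference of -3.40 ± 0.49 (adjusted p = 1.01e-05). ENSGACG00000012640 differed by -2.68 ± 0.21 (adjusted p = 1.71e-09). Library both replicate 7, labelled male, had female values of these genes, with 34 reads of ENSGACG00000013963 where the mean of the other males corresponds to 1040. Without it 520 genes were called, 466 higher in females. Limma-voom called 883 genes, 578 higher and 305 lower, a smaller share of higher genes than in the main test.

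**Figure D4:**
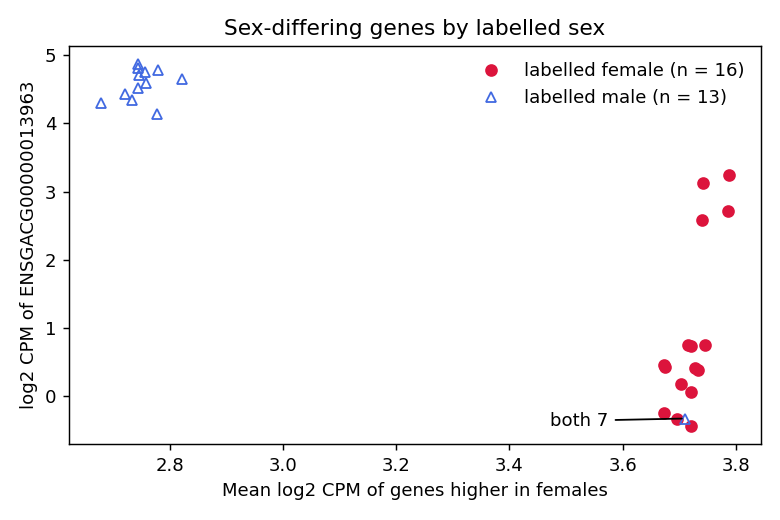
Mean log2 CPM of 426 genes higher in females, chosen without both replicate 7 (x axis), against log2 CPM of ENSGACG00000013963 (y axis), 1 point per library, by labelled sex. The library both replicate 7, labelled male, lies among the 16 libraries labelled female.

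Whether the exposure effects differed between the sexes was tested from the group-by-sex means. The males with both exposures include both replicate 7, which had female values of the sex-differing genes. Without that library limma called 0 genes in each of these tests. For the average paternal effect limma and limma-voom called 0 genes, with 892 at an unadjusted p under 0.05. That number was 2923 without neither replicate 2, 1839 without neither replicate 5 and 545 without neither replicate 1, and without neither replicate 4 a single gene was called, ENSGACG00000016127, at 3.90 ± 0.51 (adjusted p = 0.00118), named after its values were seen. Without replicate 1 or replicate 4 the neither females are a single fish, which is assumed to vary like the other groups. ENSGACG00000003949 had the smallest p-value, with a female effect above the male effect by 0.61 ± 0.15, and ENSGACG00000001542 led the other side with -0.75 ± 0.21 (adjusted p = 0.749 for each). For the average personal effect both tools called 0 genes, with 428 at an unadjusted p under 0.05 and 1115 without neither replicate 5. ENSGACG00000009205 had a difference of 0.73 ± 0.19 and ENSGACG00000004664 one of -1.15 ± 0.33 (adjusted p = 0.992 for each).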

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

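All tests of explanations in this part were chosen after the results were seen. Values far from the rest of their group were sought in 168 sets of library measures and gene values, and 18 were found, 7 of them in neither replicate 3. Chance alone picks out about 1 set in 20.

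Neither replicate 3 stood apart in 3 library measures. Its relative log spread was 1.52 against 0.267 to 0.338 in the other neither libraries, its table sum was 61.2% of the scaled library size against 45.0% to 46.4%, and its 10 genes with most reads took 5.68% of reads against 3.40% to 3.81%. Tables argue against low depth, since the 6 libraries with fewer reads reached a spread of at most 0.42, and against the lane, whose 5 other libraries reached at most 0.443. A few abundant genes would have to take the excess of 15.4 percentage points of the scaled library size in the table sum. The 10 genes with most reads took 1.94 points more than in the median library, as a share of reads in the table. The bases of these shares differ, and larger sets of genes were not counted. Group, father and sex are shared with neither replicate 2, whose spread was 0.267. As far as this single library can show, these labels alone do not account for it. Dissection or RNA quality may remain, which cannot be told apart without gene symbols or gene models, and other causes were not tested. Of the abundant genes, 34.6% lay over 2-fold from the median of the other libraries, 15.7% above and 18.8% below, where no other library exceeded 3.22%.

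In the same library 4 named genes lay far from the rest of the group. ENSGACG00000013161 had 1.68 log2 CPM against 2.72 to 2.92, ENSGACG00000010285 had 5.53 against 4.44 to 4.72, ENSGACG00000016981 had 4.32 against 3.43 to 3.66, and ENSGACG00000010807 had 1.54 against 3.11 to 3.65.

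Both replicate 7 is labelled male. On a scale of 426 genes higher in females, chosen without this library, with the mean of the 12 other males at 0 and of the females at 1, it lay at 0.988. The libraries labelled female spanned 0.949 to 1.07 and the other males -0.0745 to 0.073. A mixture of male and female tissue is argued against by ENSGACG00000013963, whose reads had an upper 95% Poisson bound of 0.0458 of the mean of the other males. This gene replaced the first one tried, which the naming rule did not cover, after both were seen; the first gave a bound of 0.0875. A swap with a library labelled female would need a partner at male level, and 0 of the 16 were below 0.5. A wrong entry of sex, an exchange with a fish outside these libraries, or a difference between recorded and genetic sex may account for it and stays open. In this library ENSGACG00000014142 had 4.79 log2 CPM against 4.1 to 4.27 in the others of the group.

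Neither replicate 5 and personal only replicate 5, both males of father M33 from lane 6, were closer to each other than any other pair. Their spread beyond read sampling was 5.65%, where the smallest of 405 other pairs was 9.35%. A single library sequenced in portions is argued against by a variance of 1.86 times read sampling, since 100 random divisions of their pooled reads gave 0.93 to 1.06. Shared father and sex is argued against as the whole cause, since 0 of 13 other such pairs were as close, nor any of the 11 without both replicate 7 (smallest 10.4%), whose sex is in doubt. Libraries made from the same fish might give such values and cannot be told apart here from close siblings, since no genotypes were used. Of the 13 pairs, 1 also shared the lane, and that pair is 1 of the 2 with both replicate 7.

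The remaining values are single genes or depths. Paternal only replicate 8 had 26896865 reads against at most 13464189, and both replicate 5 had 55155451 against at most 19835515. ENSGACG00000004905 had 5.44 in paternal only replicate 7 against 4.89 to 5.09, and 4.71 in personal only replicate 1 against 4.93 to 5.12. ENSGACG00000010285 had 3.65 in paternal only replicate 3 against 4.08 to 4.39. ENSGACG00000015268, which leads the interaction, had -0.99 in personal only replicate 5 against 0.75 to 2.01. ENSGACG00000015856 had -6.77, the floor of 0 reads, in personal only replicate 8 against -3.54 to -0.72. In the group with both exposures, ENSGACG00000016177 had 2.85 in replicate 1 against 3.48 to 3.81, ENSGACG00000015028 had -3.97 in replicate 2 against -1.23 to 0.46, and ENSGACG00000009205 had 2.50 in replicate 3 against 3.07 to 3.43.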

How the results depend on the processing

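Settings that leave out both replicate 7 or personal only replicate 5 by name, also with other libraries, were chosen after seeing the data. So were limma-voom and the correlations of fold changes with a library left out. Leaving out each father, and so all of his libraries, was fixed beforehand. Of 413 alternative counts, 367 equalled the main count or stayed within 1.5 times of it, and 46 did not. Where the main count was 0, only another 0 was taken as equal. That holds for every comparison but both versus neither and female versus male. Of 1393 alternative values of named genes, 1338 kept direction and side of the threshold, 36 lost it, 19 gained it and 0 reversed. Most of these genes were not past the threshold in the main fit and were picked as the most extreme. Keeping side and direction was therefore likely beforehand. Of the 36 losses, ENSGACG00000020611 had 16 and ENSGACG00000005494 had 19, in both versus neither. The causes were not tested except where named.

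Both versus neither went from 2 genes to 0 with 1 value per father and personal condition, with lane as a covariate, with only the 2 groups compared and in limma-voom, to 1 in limma-voom without neither replicate 3, and to 4, both genes among them, without the 3 doubted libraries. Leaving out 1 neither library or 1 father gave 0 to 5. Over 35 alternatives ENSGACG00000020611 passed in 19, with adjusted p from 0.00631 to 0.505, and ENSGACG00000005494 in 16, from 0.0247 to 0.505. Their log2 changes were 0.97 to 1.46 and 0.87 to 1.35, so the lost calls do not show that the differences went away. The 0.97 was on a scale of log2(CPM + 1). All alternatives refit the same fish for genes picked by their calls, so similar changes are no independent support. Paternal only versus neither went from 0 to 1 under quantile normalization and under library weights, and leaving out 1 neither library or father gave 0 to 3. Personal only versus neither gave 0 to 975 in that way. The 975 came without neither replicate 2 and with neither replicate 3 kept. Leaving out father M8, and so both of these libraries, gave 0. Both versus personal only went from 0 to 1 without the father block, under library weights and without neither replicate 3 and both replicate 7, to 2 in limma-voom and to 5 in limma-voom without neither replicate 3, and single omissions gave 0 to 1. The average paternal effect went from 0 to 2 under library weights, without neither replicate 3 and both replicate 7, without the 3 doubted libraries and in limma-voom without neither replicate 3, with 0 to 1 for single omissions. The interaction went from 0 to 1 in limma-voom with and without neither replicate 3. Sex by the average paternal effect gave 0 to 1 for single omissions.

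Female versus male went from 525 to 793 under library weights, 883 in limma-voom and 1239 in limma-voom without neither replicate 3, with 444 to 607 for single omissions. The 793 included 515 of the 525. Correlations fell from 0.771, 0.77 and 0.73 to 0.148, 0.228 and 0.119 with divided controls, and were 0.62, 0.671 and 0.623 without neither replicate 3. Shared calls went from 0 to 367, 459 and 288 at an unadjusted p under 0.01. A fixed father block gave 0 calls for the personal comparisons and the interaction, and 447 for sex. Genes with few reads limit the called genes, which had as few as 8 and 12 reads in a library.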

Other observations

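The test of fathers was set before its result was seen; the other tests in this part were chosen after. Libraries of different fathers differed in the expression of some genes. A limma F test over 8 contrasts between fathers within paternal exposure, with group and sex in the fit, called 211 genes, with 2358 at an unadjusted p under 0.05. Of 100 assignments of fathers to libraries within groups, the real one included, 1 gave as many called genes, and the highest other gave 8. Chance is therefore unlikely for this count but not excluded, since 1 of 100 is the smallest share possible here. At an unadjusted p under 0.05 another assignment gave 2404 genes, more than the real one. Without neither replicate 3 the count was 512 (highest other 12), and without the 3 doubted libraries 339 (highest other 69). Lane was not in this fit, and the labels do not say whether siblings shared a tank.

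Genes higher in females clustered near 2-fold. Without both replicate 7, of 197 called genes higher in females with a standard error under 0.1, 123 lay at a log2 difference of 0.8 to 1.2 and 53 at 0.4 to 0.8, with a median of 0.89. Of 26 called genes higher in males with the same precision, 2 lay in each of these ranges and 21 at 0.2 to 0.4. A candidate explanation is that females carry 2 copies of these genes and males 1. The 123 genes prompted this hypothesis and so do not test it, and no chromosome positions were used.

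ENSGACG00000013963, higher in males, had 2 levels among the fish labelled female. Paternal only replicate 2, personal only replicate 9, both replicate 2 and both replicate 5 had 3.12, 2.71, 2.59 and 3.24 log2 CPM, and the other 12 had -0.44 to 0.75. These 4 fish had different fathers.

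A paternal effect that acts alike in unexposed and exposed offspring would make paternal only versus neither correlate with both versus personal only, which share no libraries. They share fathers, however, so resemblance of siblings would do the same, and the random signs of the simulated sets do not keep siblings together. Across genes r was 0.206, and 11 of 100 simulated sets without effects gave an r as high, so such an effect may exist but cannot be told apart from chance or from resemblance of siblings. Without neither replicate 3 r was 0.289, with 4 of 100 as high. The corresponding personal effect, from personal only versus neither and both versus paternal only, gave r = -0.037, with 60 of 100 simulated sets as high. Without neither replicate 3 this r was 0.079, with 33 of 100 as high.

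Other splits of the libraries into groups of the same sizes, 100 in each case with the real one included, were counted for each comparison. For female versus male 1 of 100 splits called as many as 525 genes (highest other 22), and for both versus neither 1 of 100 called as many as 2 (highest other 1). Chance is unlikely for the count by sex, though 1 of 100 is the smallest share these splits can give. For both versus neither the splits moved libraries across fathers, and with 1 value per father and personal condition 0 genes were called, so chance among fathers is not excluded. For every other comparison the real count was 0, which no split can undercut, so the 100 of 100 splits as large say nothing about chance. The highest other count was 5 for paternal only versus neither, 1 for personal only versus neither, 1 for the interaction, 125 for both versus paternal only, 25 for both versus personal only, 1 for paternal only versus personal only, 1 for the average paternal effect, 11 for the average personal effect, 1 for sex by paternal effect and 0 for sex by personal effect. The split with 125 genes may point to a structure among the samples, but none was tested for, and chance among correlated genes could also give it; it was 1 of 3 other splits with any call in that comparison.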
